A study of Danio rerio with 40 samples.

How the data were processed

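Poly-A RNA of whole zebrafish embryos and larvae was sequenced by the study in 40 libraries, 5 in each of 8 groups. Per the labels, sets of 25 to 30 embryos were kept in 300 pM 1α,25-dihydroxyvitamin D3 or in ethanol vehicle starting at 24 h after fertilization, with fresh medium every 24 h and 0.003% phenylthiourea against pigment, and were collected at 2, 4, 6 or 7 days post fertilization (dpf). The labels also mention another experiment, in which larvae were exposed only at 6 dpf and for 24 h. No library is marked as coming from it, so the length of exposure at 6 and 7 dpf is taken from the main protocol and is not certain. Reads were 51 bases long and sequenced from both ends. The labels name CASAVA 1.4 and HTSeq 0.5.3p3 without stating an order or an aligner. They place the annotation on the zebrafish assembly Zv9.

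The authors deposited a table of raw counts per gene and a table of raw counts per exon, per the labels without normalization. The gene table holds whole-number counts for 14267 genes in all 40 libraries and is the source of every comparison. It holds 14211 distinct gene symbols, 56 of them on more than 1 gene; 4429 genes carry a placeholder symbol. The symbols of 13693 genes matched the reference tables. The exon table holds 194750 exons, of which 26551 carry a gene name and 168199 do not. After the named exons, 8 of its columns are blank and 32 are complete. The blank columns are number 1 of each group in that table, which are the shallow libraries, replicate 1 in vehicle and 5 in treated groups of the gene table. Its named exons belong to 10232 genes and were used only in an alternative, and the exons without a gene name enter no comparison.

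Replicate numbers are those of the gene table. The exon table numbers the treated libraries differently. Genes with equal totals of at least 50 counts in both tables matched each exon-table column to 1 gene-table library. Treated replicate 5 of the gene table is number 1 in the exon table, and treated replicates 1 to 4 are numbers 2 to 5. Total counts ranged from 67235165 to 214502251 per library. No 2 libraries of a group differ by sampling noise alone: the smallest chi-square per degree of freedom over 80 pairs was 21.8. Replicate spread, not counting error, therefore limits the precision of each value.

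Groups were taken from the labels. Each age was compared separately, treated against vehicle, in edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM factors, estimateDisp, glmQLFit with robust estimation and glmQLFTest. Adjusted p-values are Benjamini-Hochberg (BH) over the genes tested, with a threshold of 0.05. Log2 fold changes come from these models and are given ± SE. Levels are counts divided by library size (CPM) with TMM factors over all 40 libraries, given as mean ± SD of 5 libraries. Vehicle libraries of neighbouring ages were compared by the same steps. A test of whether the response differs between ages used all 40 libraries and the 3 interaction coefficients together, followed by the 6 differences between pairs of ages. A gene is called separated where all 5 libraries of one group lie above all 5 of the other. Chance gives this for 0.79% of genes if the libraries are exchangeable.

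Gene lists were fixed before the data were examined: 23 lists with 787 members, of which 582 matched the gene table. They cover vitamin D signalling and metabolism, calcium and phosphate handling, bone and mineral matrix, cartilage, glycolysis and gluconeogenesis, cholesterol biosynthesis, fatty acid synthesis and oxidation, circadian clock, stress and unfolded protein response, immune and acute phase, retinoid and pigment, cell cycle, and insulin, IGF and thyroid axes. The other lists mark tissues of a whole larva: exocrine pancreas, liver, intestine, photoreceptors, lens, fast and slow muscle, red blood cells, ionocytes, epidermis, and neurons and glia. Some genes stand on more than 1 list. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, BH over the lists of an age. Alternatives were camera with an estimated correlation and fry, which tests whether a list moves in 1 direction without comparing it with other genes.

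The rule for named genes was also written before the data were examined. It takes up to 10 genes each way at each age, among those past the threshold that are separated, have a symbol that is not a placeholder and a mean log2 CPM of at least 2, by size of fold change. It adds cyp24a1, vdra and vdrb at every age and the 10 smallest interaction p-values. For the vehicle ages it takes 5 genes each way at a log2 CPM of at least 5, and for each list up to 4 members with the smallest p. Other list members that are named were chosen after their values were seen, as were the genes named from the blocked fit at 4 dpf. Those list members were run under the same alternatives as the others.

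Alternatives fixed in advance were RLE and upper quartile factors, no filter (at least 1 count), a stricter filter (1 CPM in at least 5 libraries), DESeq2 1.42.0, limma voom with quality weights, a block for the replicate number, gene totals from the named exons, 1 fit of all 40 libraries and leaving out each library in turn. Added after seeing the data were a fit without the shallow library of each group, a block by the exon table's replicate numbers, and a DESeq2 likelihood ratio test in place of the planned Wald test of the interaction, which was not run. The steps were tested on simulated data with planted changes. Of planted 2-fold changes 90% to 93% were recovered at each age, and of 1.5-fold changes 46% to 63%; 1.86% to 4.79% of calls were false. For the interaction 82% were recovered with 5.75% false calls. A planted list was called at each age with 0 other lists. The simulation drew each gene independently, with no correlation between genes and no structure shared by libraries. Its rates of recovery and of false calls therefore do not carry over to the data. There other splits of the libraries called up to 19 lists at 7 dpf. A 7.22-fold rise of cyp24a1 at 4 dpf, with the groups separated, did not pass.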

Results

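RNA of whole zebrafish embryos and larvae was measured in 40 libraries, 5 from each of 8 groups: animals kept in 300 pM 1α,25-dihydroxyvitamin D3 (calcitriol, the hormone form of vitamin D) or in ethanol vehicle, and collected at 2, 4, 6 or 7 days post fertilization (dpf). Total counts ranged from 67235165 to 214502251 per library. In each group 1 library was shallower than the rest, with at most 81298182 counts against at least 106850887. It is replicate 1 in each vehicle group and replicate 5 in each treated group, and is called the shallow library here. Between 13538 and 13931 of 14267 genes were detected per library. After a log2 fold change, ± gives the SE, and after a level in CPM (normalised read counts relative to library size) it gives the SD, with n = 5 libraries per group. The p-values measure only the spread between these libraries, since the labels do not say whether the libraries of a group came from separate clutches. Chi-square per degree of freedom at 2 dpf was 78.6 for vehicle replicates 2 and 3 and 64.1 for 4 and 5. Across these pairs it was 222 to 347. In treated embryos it was 30.4 for replicates 1 and 2, 40.6 for 3 and 4, and 269 to 303 across. The same pairs were closest at 4 dpf, and at 6 and 7 dpf the gap was smaller or absent. The 5 libraries of a group may therefore stand for fewer independent units, and p-values may be too small. Fold changes are relative to TMM scaling: with no scaling factors the median log2 fold change of all genes was 0.135 at 6 dpf and 0.178 at 7 dpf, and the share of called genes that were higher moved from 40.9% to 74.0% and from 50.8% to 78.2%.

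**Figure D1:**
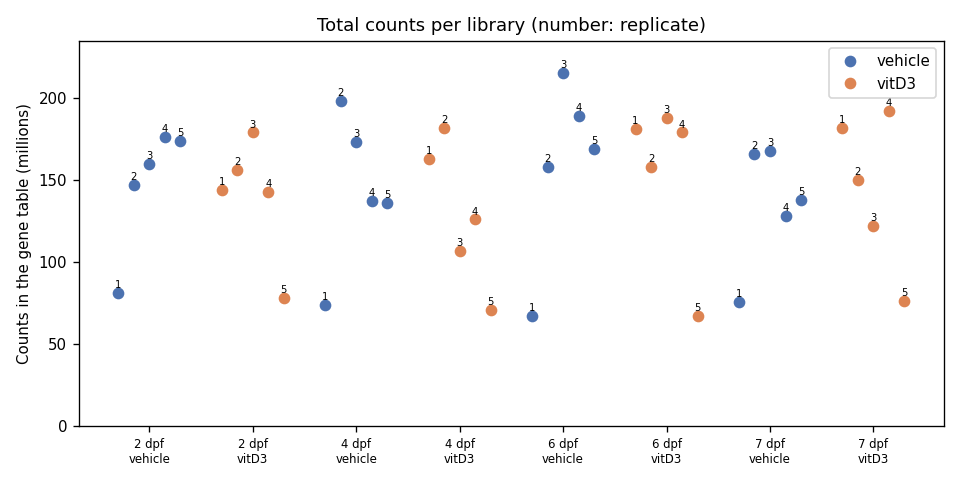
Total counts in the gene table (vertical axis, in megacounts) for each of the 40 libraries, by age and treatment, with the replicate number above each point. In each group 1 library holds 67235165 to 81298182 counts and the others at least 106850887.

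The comparison at 2 dpf asks which transcripts respond early in the treatment. The gene cyp24a1 (chromosome 6), which encodes the 24-hydroxylase that inactivates calcitriol and is a textbook target of the vitamin D receptor, rose 6.77-fold. Its level was 3.11 ± 1.07 CPM in vehicle and 21.2 ± 7.87 CPM in treated embryos, a log2 fold change of 2.76 ± 0.33 (edgeR, adjusted p = 0.0281), and all 5 treated libraries lay above all 5 vehicle libraries. It was the 1 gene of 13203 tested that passed, and 110 genes had an unadjusted p under 0.05. Separated genes numbered 32, or 0.242% of those tested, below the 0.79% that chance gives for exchangeable libraries. That share is therefore only a rough guide in these libraries, at the other ages too. The vitamin D receptor genes vdra and vdrb had log2 fold changes of -0.13 ± 0.25 and -0.10 ± 0.16, with adjusted p = 1 for each. In the fixed lists, 1 of 15 members of vitamin D signalling and metabolism rose (cyp24a1, also 1 adjusted over the list alone) and 0 members of any other list passed. The list of fast and slow muscle, with 32 members measured and a median log2 fold change of -0.07, was lower as a set by camera (adjusted p = 0.00825), with adjusted p = 0.961 with an estimated correlation. For the other 22 lists the camera adjusted p was 0.153 or more. In the block by the exon table's numbers vitamin D signalling and metabolism (0.000136, range over the alternatives 2.85e-05 to 0.99) and cholesterol biosynthesis (0.01, range 0.000264 to 0.99) passed as well, and neither held there with an estimated correlation (0.193 and 0.903). The median of the vitamin D list in that block was -0.01, and 1 of its 15 members, cyp24a1, passed. Median, mean and test differed in sign for glycolysis and gluconeogenesis (median 0.01, mean -0.01, up), for fatty acid synthesis and oxidation (0.01, 0, down), for immune and acute phase (0.01, -0.08, down), for red blood cells (-0.03, 0, up) and for retinoid and pigment (0, -0.01, up).

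The call of cyp24a1 at 2 dpf was lost without vehicle replicate 1 (0.0515), 2 (0.121), 3 (0.113), 4 (0.12) or 5 (0.158) or treated replicate 1 (0.0969), 2 (0.105), 3 (0.102) or 4 (0.0892). Over all alternatives its adjusted p ranged from 9.96e-16 to 0.158. The call of the muscle list was lost without vehicle replicate 1 (adjusted p = 0.202) or 4 (0.132), or treated replicate 3 (0.34) or 4 (0.0849), and with fry (0.984), over a range of 2.71e-05 to 0.984. The number of lists past the threshold was 5, 2, 3 and 4 without vehicle replicate 1, 2, 4 and 5, and 2, 2 and 9 without treated replicate 1, 4 and 5.

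At 4 dpf the level of cyp24a1 was 34.2 ± 11.8 CPM in vehicle and 247 ± 112 CPM in treated larvae, again with all 5 treated libraries above all 5 vehicle libraries, a log2 fold change of 2.85 ± 0.40 with adjusted p = 0.0981. It passed without vehicle replicate 1 (0.0456) and without treated replicate 5 (0.00478), with a range over the alternatives of 1.5e-06 to 0.353. The comparison called 0 of 13410 genes in edgeR, with 924 genes at an unadjusted p under 0.05. DESeq2 called 100 genes, limma voom with quality weights 30, and 1 fit of all 40 libraries 27; leaving out vehicle replicate 1 gave 8 genes and leaving out treated replicate 5 gave 9. Separated genes numbered 236, or 1.76% of those tested, against the 0.79% that chance gives. The receptor genes vdra (-0.60 ± 0.24, adjusted p = 0.643) and vdrb (-0.62 ± 0.16, adjusted p = 0.325) did not pass.

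A fit at 4 dpf with a block for the exon table's replicate numbers, chosen after the data were seen, called 1255 genes, 700 higher and 555 lower in treated larvae. In that fit cyp24a1 had a log2 fold change of 2.77 ± 0.21 (adjusted p = 0.00411). Higher as well were igfbp1b (1.81 ± 0.21, adjusted p = 0.0111), which encodes a binding protein for insulin-like growth factors, tat (1.49 ± 0.23, adjusted p = 0.0228), which encodes tyrosine aminotransferase, and the transcription factor gene klf11a (1.12 ± 0.13, adjusted p = 0.00698). Lower were the pancreatic elastase genes ela2 (-1.39 ± 0.24, adjusted p = 0.0312) and ela3l (-1.34 ± 0.16, adjusted p = 0.0108), the keratin gene cyt1l (-1.0 ± 0.07, adjusted p = 4.94e-05) and pparaa (-0.87 ± 0.07, adjusted p = 3.72e-05), which encodes a nuclear receptor for fatty acids. In the blocked fit vdra (-0.67 ± 0.12, adjusted p = 0.0126) and vdrb (-0.62 ± 0.08, adjusted p = 0.00187) were also lower. Without a block, klf11a and cyt1l passed on leaving out treated replicate 5 (0.00517 for each, ranges 2.32e-05 to 0.402 and 2.29e-05 to 0.402) and pparaa on leaving out vehicle replicate 1 (0.0482, range 3.23e-05 to 0.402).

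Genes of the cell cycle list lay together above their vehicle levels at 4 dpf: the median log2 fold change of 31 members was 0.32, 0 members passed over all genes, and 16 were higher and 0 lower adjusted over the list alone. In the block by the exon table's numbers 25 of the 31 rose over all genes and 31 adjusted over the list alone. The replication genes mcm2 (0.33 ± 0.06) and mcm5 (0.34 ± 0.08) had adjusted p-values of 0.168 and 0.3 over all genes, and 0.00133 for each in the block. Camera gave the list adjusted p = 4.62e-24, with adjusted p = 0.173 with an estimated correlation. By camera 12 lists passed at 4 dpf, 5 up and 7 down, and 0 of them passed with an estimated correlation. The other lists that were higher were bone and mineral matrix (median 0.09, adjusted p = 0.000431), stress and unfolded protein response (0.09, adjusted p = 0.0189), red blood cells (0.16, adjusted p = 0.0408) and retinoid and pigment (0.00, adjusted p = 0.0408). With an estimated correlation their adjusted p = 0.173, 0.173, 0.503 and 0.173. Lower as a set were cholesterol biosynthesis (median -0.28, adjusted p = 6.03e-05), exocrine pancreas (-0.51, adjusted p = 0.000431), fatty acid synthesis and oxidation (-0.09, adjusted p = 0.00934), insulin, IGF and thyroid axes (-0.11, adjusted p = 0.0201), calcium and phosphate handling (-0.10, adjusted p = 0.0219), epidermis (0.02, adjusted p = 0.0401) and liver (-0.07, adjusted p = 0.0408). With an estimated correlation their adjusted p = 0.476, 0.503, 0.503, 0.503, 0.476, 0.476 and 0.608. Adjusted over the list alone, 3 members of the epidermis list were lower, among them krt4 (-0.43 ± 0.06), which passed over all genes without treated replicate 5 (0.0263, range 6.74e-06 to 0.806). The epidermis list had a positive median and a mean of -0.10, the retinoid list a median of 0.00 and a mean of 0.06. Vitamin D signalling and metabolism, not called, had a median of -0.06, a mean of 0.04 and a camera direction down.

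Of the 12 lists at 4 dpf, cell cycle, bone and mineral matrix, and cholesterol biosynthesis passed on leaving out any 1 library, and each of the other 9 was lost on leaving out at least 1. Without treated replicate 5, 4 lists passed, and exocrine pancreas had adjusted p = 0.0833, calcium and phosphate handling 0.0574, fatty acids 0.0743, liver 0.518, red blood cells 0.14, epidermis 0.0743, retinoid and pigment 0.0743, and insulin, IGF and thyroid axes 0.339. Without vehicle replicate 2, 7 lists passed; the losses were calcium and phosphate handling (0.0874), fatty acids (0.105), liver (0.809), epidermis (0.0855), retinoid and pigment (0.0773), and insulin, IGF and thyroid axes (0.139). Without vehicle replicate 1 the stress list had 0.0829, red blood cells 0.073 and retinoid and pigment 0.0676. Without vehicle replicate 3 liver had 0.197, red blood cells 0.0602, epidermis 0.0613, and the retinoid and insulin lists each 0.0518. Leaving out vehicle replicate 4 gave calcium and phosphate handling 0.052 and liver 0.119, and leaving out vehicle replicate 5 gave red blood cells 0.0982 and retinoid and pigment 0.0604. Red blood cells were also lost without treated replicate 1 (0.0895) or 2 (0.135), epidermis without treated replicate 3 (0.156), and retinoid and pigment without treated replicate 4 (0.0884). In the block by the exon table's numbers liver (0.0859, range over the alternatives 4.53e-07 to 0.809), red blood cells (0.0512, range 0.000769 to 0.503) and insulin, IGF and thyroid axes (0.0557, range 0.000473 to 0.503) were lost. In that block circadian clock (0.00172, range 3.81e-05 to 0.637), intestine (0.0463, range 0.000132 to 0.809) and muscle (0.0463, range 0.012 to 0.503) passed, and with an estimated correlation in the same block each was lost (0.49, 0.63 and 0.511).

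**Figure D2:**
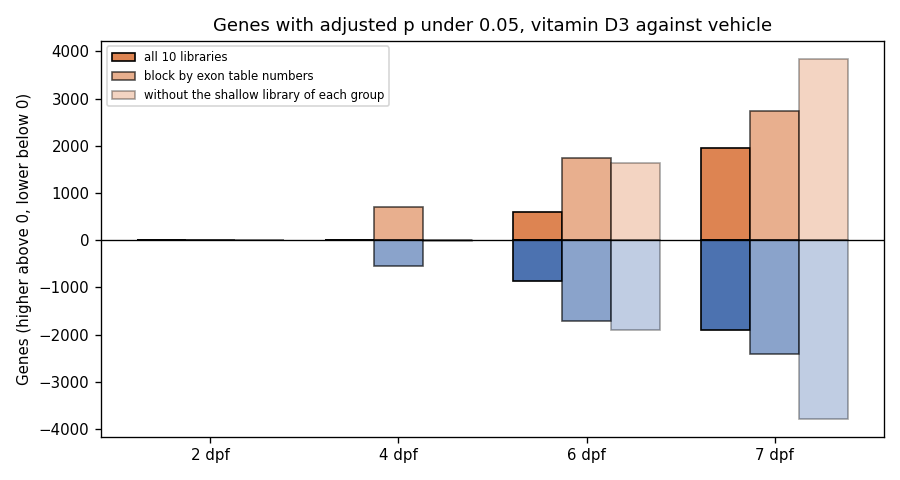
Number of genes with adjusted p under 0.05 (vertical axis, higher in treated animals above 0, lower below 0) at each age, for all 10 libraries of an age, with a block by the exon table's replicate numbers, and without the shallow library of each group. At 4 dpf the bars hold 0, 1255 and 18 genes, at 6 dpf 1444, 3457 and 3532, and at 7 dpf 3866, 5152 and 7626.

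At 6 dpf the largest rises among the genes named by rule were in cyp24a1, igfbp1b and klf11a, and the largest falls in rh50, ces3 and ahsg. The gene cyp24a1 rose from 162 ± 64.9 to 1273 ± 436 CPM, a log2 fold change of 2.99 ± 0.31 (edgeR, adjusted p = 0.000159). Next in size were igfbp1b (chromosome 2), which rose 7.40-fold (2.89 ± 0.32, adjusted p = 0.000236), and klf11a (chromosome 20), which rose 5.11-fold from 33.8 ± 7.22 to 171 ± 35.6 CPM (adjusted p = 2.63e-05). The other 7 genes with the largest rises were adm2 (the peptide adrenomedullin 2, 3.38-fold), tat (3.23-fold), elna (elastin, 3.18-fold), igfbp1a (2.81-fold), cyp2k6 (a cytochrome P450, 2.80-fold), slc1a4 (a neutral amino acid transporter, 2.69-fold) and pfkfb3 (a regulatory enzyme of glycolysis, 2.37-fold), each with adjusted p = 0.00511 or less. Among the falls, rh50 (chromosome 8) dropped from 12.7 ± 0.46 to 2.06 ± 0.84 CPM (6.20-fold lower, adjusted p = 6.95e-05). The plasma protein genes ahsg (fetuin A, 5.21-fold lower), c3b (complement component, 4.64-fold lower) and tfa (transferrin, 4.38-fold lower) fell, as did the keratin gene cyt1l (4.57-fold lower), the elastase gene ela3l (3.58-fold lower), ces3 (a carboxylesterase, 5.71-fold lower), cyp2k18 (4.33-fold lower) and f7i (3.77-fold lower). In comtd1, with a fall of 3.75-fold (adjusted p = 0.0276), the call was lost on leaving out vehicle replicate 4 (0.0546) or 5 (0.0666) or treated replicate 1 (0.0716), 2 (0.0664), 3 (0.0545) or 4 (0.0642), with a range over the alternatives of 4.27e-05 to 0.0716. Without treated replicate 5 the log2 fold change of ces3 moved from -2.51 to -3.12 and that of comtd1 from -1.91 to -2.57. In these 20 genes all 5 treated libraries lay on one side of all 5 vehicle libraries. Neither vdra (-0.50 ± 0.29, adjusted p = 0.332) nor vdrb (-0.58 ± 0.24, adjusted p = 0.16) passed, but both did without vehicle replicate 1 (0.0377 and 0.0105), in the block by the exon table's numbers (0.00313 and 0.00102), without the shallow libraries (0.00169 and 0.00043) and in limma voom (0.0113 and 0.00485), over ranges of 0.00169 to 0.557 and 0.00043 to 0.324.

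The comparison at 6 dpf called 1444 of 13505 genes, 590 higher and 854 lower; 246 changed at least 2-fold, 63 higher and 183 lower. Separated genes were 1329, or 9.84%, against 0.79% by chance. The block by the exon table's numbers called 3457 genes, 1436 of the 1444 among them, and the fit without the shallow libraries called 3532, with 1437 of the 1444. Leaving out 1 library moved the count by over 1.5 times for vehicle replicate 4 (874 genes) and 5 (940) and for treated replicates 1 (894), 3 (960), 4 (849) and 5 (2310).

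Genes of digestive organs fell together at 6 dpf. Of 27 liver list members 17 fell, 1 rose (rbp4, 0.29 ± 0.08) and 9 did not pass (21 fell and 1 rose adjusted over the list alone). Examples are ahsg (-2.38 ± 0.23), tdo2a (-0.91 ± 0.13) and serpina1 (-0.84 ± 0.13). The liver list had a camera adjusted p = 8.66e-17, with adjusted p = 0.0536 with an estimated correlation. In the intestine list 13 of 19 members fell and 0 rose (15 fell adjusted over the list alone), among them the peptidase gene dpp4 (-0.78 ± 0.09), the glucose transporter gene slc5a1 (-0.83 ± 0.11) and the claudin gene cldn15la (-0.80 ± 0.11). Its camera adjusted p = 1.76e-14 and adjusted p = 0.0116 with an estimated correlation. Of 16 exocrine pancreas members 9 fell and 2 rose (10 and 2 adjusted over the list alone). The elastase and carboxypeptidase genes ela3l (-1.84 ± 0.17), ela2 (-1.73 ± 0.22) and cpa5 (-1.19 ± 0.17) fell, while ptf1a (0.62 ± 0.12), a transcription factor of the pancreas, was among those that rose. Camera gave adjusted p = 4.48e-09, with adjusted p = 0.233 with an estimated correlation. The call of rbp4 was lost without vehicle replicate 1 (0.0597), 3 (0.11), 4 (0.0881) or 5 (0.101) or treated replicate 1 (0.113), 2 (0.0898), 3 (0.119) or 4 (0.0937), with a range over the alternatives of 0.0034 to 0.119, and also with RLE factors, the replicate block and 1 fit of all 40 libraries.

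The lists of fatty acids, glycolysis, cholesterol biosynthesis and the insulin, IGF and thyroid axes were also lower at 6 dpf. In fatty acid synthesis and oxidation 11 of 25 members fell and 2 rose (15 and 3 adjusted over the list alone). The elongase gene elovl2 (-1.71 ± 0.15), pparaa (-1.06 ± 0.10) and the fatty acid transporter gene cd36 (-1.05 ± 0.12) fell, and scd (1.16 ± 0.32) and lipc (0.86 ± 0.23) rose. Camera gave the fatty acid list adjusted p = 1.31e-10 and adjusted p = 0.00318 with an estimated correlation. Glycolysis and gluconeogenesis had 10 falls and 0 rises among 37 members (15 and 0 adjusted over the list alone), including the glucose transporter gene slc2a2 (-1.05 ± 0.07) and the pyruvate kinase gene pklr (-1.83 ± 0.13). Its adjusted p = 1.31e-10, with adjusted p = 0.0513 with an estimated correlation. For cholesterol biosynthesis 7 of 21 members fell and 0 rose (10 and 0 adjusted over the list alone), including dhcr7 (-0.76 ± 0.11) and cyp51 (-0.89 ± 0.18). Its adjusted p = 0.0026, with adjusted p = 0.247 with an estimated correlation. In the list of insulin, IGF and thyroid axes 11 of 35 members fell and 4 rose (12 and 7 adjusted over the list alone). The genes for insulin (ins, -1.74 ± 0.18), the iodide transporter (slc5a5, -1.35 ± 0.14) and a deiodinase (dio1, -1.32 ± 0.18) fell, and igfbp1b, igfbp1a, igf2b (1.09 ± 0.21) and igf2a (0.62 ± 0.16) rose. The camera adjusted p = 0.00217, with adjusted p = 0.233 with an estimated correlation; it was 0.1 without treated replicate 5 and 0.0565 without the shallow libraries, over a range of 0.000369 to 0.233. Of the genes that rose against their list, scd was lost without vehicle replicate 2 (0.0814), 3 (0.0669), 4 (0.0928) or 5 (0.0769) or treated replicate 1 (0.0855), 3 (0.0992) or 4 (0.0964), and with the replicate block (range 0.000438 to 0.103). The gene lipc was lost without vehicle replicate 2 (0.0791) or 5 (0.082) or treated replicate 1 (0.0904) or 3 (0.0858), and with the replicate block (range 0.00307 to 0.0904). For igf2a the libraries were vehicle replicates 3 (0.0555), 4 (0.0747) and 5 (0.0739) and treated replicates 1 (0.0787), 2 (0.0645), 3 (0.0702) and 4 (0.0823), with a range of 0.000122 to 0.0823.

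Mineral handling genes changed in both directions at 6 dpf. In the calcium and phosphate list 4 of 24 members fell and 1 rose (5 and 1 adjusted over the list alone). The hormone genes stc2 (-1.41 ± 0.09) and stc1l (-0.75 ± 0.11), which encode stanniocalcins, and the phosphate transporter gene slc34a2a (-1.37 ± 0.09) fell, and pth1a (1.08 ± 0.29), which encodes parathyroid hormone, rose. The list had adjusted p = 7.57e-05, with adjusted p = 0.0536 with an estimated correlation. Among 19 bone and mineral matrix members 5 rose and 0 fell (7 and 0 adjusted over the list alone), including the matrix Gla protein gene mgp (1.48 ± 0.19) and the collagen gene col10a1 (0.73 ± 0.13). Its adjusted p = 0.00106, with adjusted p = 0.153 with an estimated correlation. The ionocyte list had 6 falls and 0 rises among 22 members (7 and 0 adjusted over the list alone), with the sodium pump gene atp1a1a.4 at -0.69 ± 0.11. Its adjusted p = 0.00048, with adjusted p = 0.272 with an estimated correlation. For vitamin D signalling and metabolism (adjusted p = 0.764) cyp24a1 rose and zgc-136333 (-0.63 ± 0.14) and gc (-0.94 ± 0.24), which encodes the vitamin D binding protein, fell among 15 members (1 and 2 adjusted over the list alone). The call of gc was lost without vehicle replicate 2 (0.0673), 3 (0.0568), 4 (0.0631) or 5 (0.0571) or treated replicate 1 (0.072), 2 (0.0572) or 4 (0.082), and in the block by the exon table's numbers (0.0563, range 4.28e-05 to 0.082). That of pth1a was lost without vehicle replicate 2 (0.0807), 3 (0.0838) or 4 (0.0631) or treated replicate 1 (0.0626), 2 (0.0778) or 4 (0.0906), with a range of 0.00226 to 0.0906. The gene zgc-136333 was lost with exon totals (0.144) and the replicate block (0.0608, range 0.000175 to 0.144), and col10a1 in 1 fit of all 40 libraries (0.0574, range 6.49e-06 to 0.0574).

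Photoreceptor genes fell at 6 dpf, 10 of 29 with 0 rises (13 and 0 adjusted over the list alone), among them the cone transducin gene gnb3b (-0.87 ± 0.20) and the cone kinase gene grk7a (-0.98 ± 0.22). Camera gave the photoreceptor list adjusted p = 1.52e-06, with adjusted p = 0.297 with an estimated correlation. Of the epidermis list 6 of 19 members fell and 1 rose (6 and 1 adjusted over the list alone). The keratin genes krt4 (-0.92 ± 0.08) and cyt1 (-1.06 ± 0.10) fell and krt18 (0.45 ± 0.12) rose; adjusted p = 0.000553, with adjusted p = 0.102 with an estimated correlation. Muscle genes fell in 8 and rose in 1 of 32 (11 and 2 adjusted over the list alone). The creatine kinase gene ckmb (-0.44 ± 0.06) fell and mybpc2b (0.73 ± 0.08) rose; adjusted p = 0.00255, with adjusted p = 0.407 with an estimated correlation. The stress and unfolded protein response list had 5 rises and 0 falls among 26 members (11 and 0 adjusted over the list alone), with sesn2 at 1.01 ± 0.22. Its adjusted p = 1.36e-05, with adjusted p = 0.188 with an estimated correlation. Cell cycle genes had a median of 0.32, with 2 of 31 higher, hells (0.67 ± 0.18) and rrm2 (0.70 ± 0.20), and 0 adjusted over the list alone. The list had adjusted p = 0.000516, with adjusted p = 0.616 with an estimated correlation, and 0.0576 without treated replicate 5, over a range of 1.24e-07 to 0.616. The call of hells was lost without vehicle replicate 2 (0.0769), 3 (0.0778), 4 (0.0829) or 5 (0.0794) or treated replicate 1 (0.0713), 2 (0.0506), 3 (0.0516) or 4 (0.0581), with a range of 3.82e-05 to 0.0829. For rrm2 the libraries were vehicle replicates 2 (0.0974), 3 (0.0844), 4 (0.085) and 5 (0.0945) and treated replicates 1 (0.103), 2 (0.102), 4 (0.051) and 5 (0.0579), with a range of 0.000768 to 0.103, and the call was lost as well with the replicate block and exon totals. That of krt18 was lost without vehicle replicate 2 (0.0815), 3 (0.077), 4 (0.0999) or 5 (0.0769) or treated replicate 1 (0.0849), 3 (0.084) or 4 (0.103), and with the replicate block and exon totals, with a range of 0.000738 to 0.122.

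Of the 23 lists 15 passed at 6 dpf. The 8 others were vitamin D signalling and metabolism, cartilage (adjusted p = 0.506, 2 rose), circadian clock (0.823, 0 passed), immune and acute phase (0.566, 2 rose and 2 fell), lens (0.506, 3 rose and 2 fell), red blood cells (0.175, 2 rose and 1 fell), neurons and glia (0.0618, 4 fell) and retinoid and pigment (0.764, 4 rose and 3 fell). In the last, rdh10a (0.47 ± 0.07) and crabp2b (0.67 ± 0.12) rose and the retinol receptor gene stra6 (-0.75 ± 0.08) fell. Median and mean differed in sign for vitamin D signalling and metabolism (-0.05 and 0.03), for lens (-0.07 and 0.02) and for retinoid and pigment (0.03 and -0.02).

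**Figure D3:**
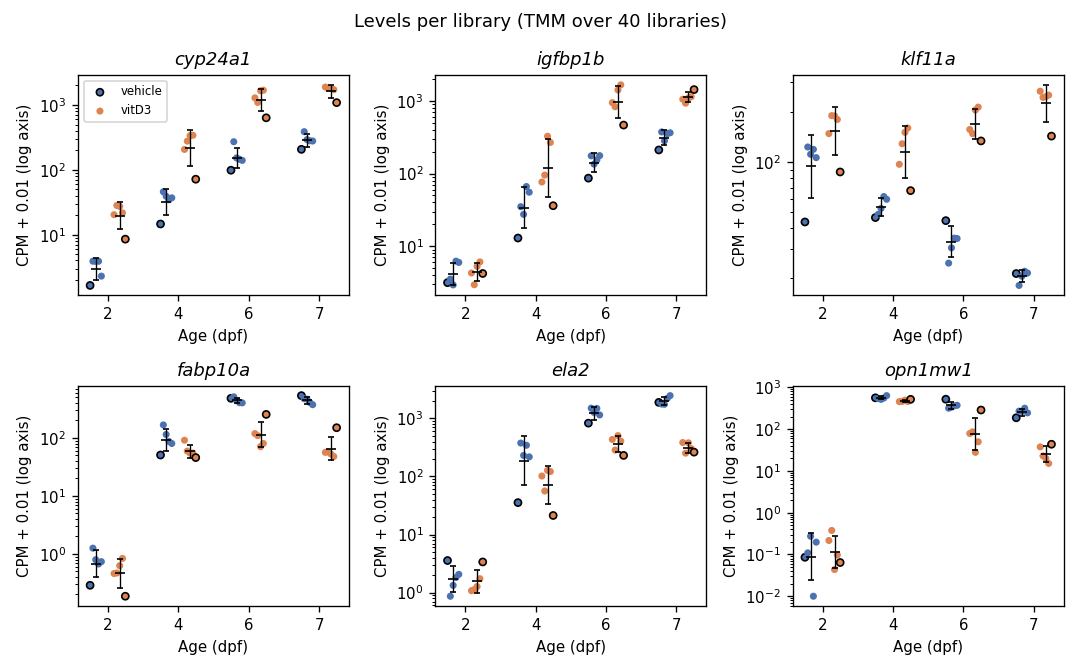
Level of 6 genes in each library (CPM plus 0.01, log axis) against age in dpf, vehicle in blue and vitamin D3 in orange; black-edged points are the shallow library of each group, and bars show the mean ± SD of log values of 5 libraries. The level of cyp24a1 in treated animals lies above vehicle at each age (21.2 against 3.11 CPM at 2 dpf, 1661 against 289 CPM at 7 dpf), while ela2 at 7 dpf is 316 against 2018 CPM.

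At 7 dpf the largest rises among the genes named by rule were in hsp70l, hsp70 and klf11a, and the largest falls in rh50, opn1mw1 and ins. The heat shock gene hsp70l (chromosome 8) rose 21.9-fold, from 3.48 ± 1.52 to 75.2 ± 41.1 CPM (4.46 ± 0.57, adjusted p = 0.000204), and hsp70 (chromosome 3) 17.5-fold, from 1.71 ± 0.70 to 29.4 ± 18.3 CPM (adjusted p = 0.000303). The gene klf11a rose 11.1-fold (3.48 ± 0.16, adjusted p = 1.49e-07), slc1a4 9.52-fold (adjusted p = 6.17e-05) and cyp24a1 5.77-fold, from 289 ± 64.6 to 1661 ± 325 CPM (2.53 ± 0.18, adjusted p = 3.79e-06). Further rises were in scd (a fatty acid desaturase, 5.90-fold), sesn2 (5.44-fold), timp2b (a metalloproteinase inhibitor, 4.73-fold), gtpbp1 (4.55-fold) and the stress transcription factor gene atf3 (4.32-fold). The green opsin gene opn1mw1 (chromosome 6) fell 9.21-fold, from 258 ± 47.4 to 27.9 ± 12.2 CPM (-3.20 ± 0.29, adjusted p = 1.56e-05), and ins (chromosome 5) 8.07-fold, from 11.8 ± 1.5 to 1.47 ± 0.57 CPM (adjusted p = 7.82e-06). Lower too were rh50 (9.40-fold), cyt1l (7.93-fold), ces3 (7.89-fold), ela2 (6.35-fold), ahsg (6.18-fold), the liver fatty acid binding protein gene fabp10a (6.18-fold), dpys (a pyrimidine catabolic enzyme, 5.92-fold) and cyp4v2 (5.83-fold), each with adjusted p = 0.00297 or less. In the treated shallow library fabp10a stood at 150 CPM against 47.7 to 57.0 CPM in the other treated libraries, and klf11a at 143 CPM against 244 to 266 CPM. Without that library (treated replicate 5) the log2 fold change of ces3 moved from -2.98 to -4.10. The receptor gene vdrb fell (-1.02 ± 0.23, adjusted p = 0.00704), and vdra had a log2 fold change of -0.59 ± 0.24 (adjusted p = 0.0896), which passed without vehicle replicate 1 (0.00385), in the block by the exon table's numbers (0.00815), without the shallow libraries (0.000152), in DESeq2 (0.0482) and in limma voom (0.000518), over a range of 0.000152 to 0.21.

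The comparison at 7 dpf called 3866 of 13434 genes, 1962 higher and 1904 lower; 628 changed at least 2-fold, 210 higher and 418 lower. Separated genes were 2435, or 18.1%, against 0.79% by chance. The block by the exon table's numbers called 5152 genes, 3731 of the 3866 among them. Without the shallow libraries 7626 genes were called, 3853 of the 3866 among them. Genes called at both 6 and 7 dpf numbered 470 higher, where independence would give 86.2, and 761 lower, where it would give 121, and 0 were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of the 2 ages had r = 0.81.

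Falls covered most members of the liver, exocrine pancreas, intestine and photoreceptor lists at 7 dpf. Liver genes fell in 23 of 27 members and rose in 0 (24 and 0 adjusted over the list alone), among them ahsg (-2.63 ± 0.13), serpina1 (-1.25 ± 0.10), tdo2a (-1.10 ± 0.09) and vtnb (-0.79 ± 0.07). The liver list had adjusted p = 4e-21 and adjusted p = 0.0322 with an estimated correlation. Exocrine pancreas genes fell in 13 of 16 members and rose in 1 (13 and 2 adjusted over the list alone). Elastase and carboxypeptidase genes fell, with ela3l at -2.53 ± 0.11 and cpa5 at -1.81 ± 0.13. The list had adjusted p = 1.72e-23 and adjusted p = 0.0424 with an estimated correlation. In the intestine list 14 of 19 members fell and 0 rose (15 and 0 adjusted over the list alone), with the fatty acid binding protein gene fabp2 at -2.23 ± 0.19 and the meprin gene mep1b at -1.56 ± 0.14. Its adjusted p = 1.35e-12 and adjusted p = 0.0322 with an estimated correlation. Photoreceptor genes fell in 20 of 29 members with 0 rises (21 and 0 adjusted over the list alone), among them the cone opsin genes opn1sw2 (-2.19 ± 0.16) and opn1sw1 (-2.46 ± 0.27). The photoreceptor list had adjusted p = 1.51e-11, with adjusted p = 0.146 with an estimated correlation. Lens genes fell in 7 and rose in 3 of 33 members (11 and 3 adjusted over the list alone), with the crystallin genes crygmx at -0.95 ± 0.22 and crygm3 at 1.16 ± 0.20. Its adjusted p = 0.00394, with adjusted p = 0.589 with an estimated correlation.

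The lists of fatty acids, glycolysis, insulin, IGF and thyroid axes, and calcium and phosphate handling were lower at 7 dpf. In fatty acid synthesis and oxidation 14 of 25 members fell and 2 rose (15 and 2 adjusted over the list alone), with pparaa at -1.21 ± 0.06, cd36 at -1.31 ± 0.09 and the lipase gene lpl at -1.26 ± 0.12. The fatty acid list had adjusted p = 1.97e-07 and adjusted p = 0.0105 with an estimated correlation. Glycolysis and gluconeogenesis had 18 falls and 2 rises among 37 members (21 and 2 adjusted over the list alone), with pklr at -2.30 ± 0.12 and the hexokinase genes hk2 (0.90 ± 0.19) and hk1 (0.39 ± 0.08) rising. Its adjusted p = 5.23e-07, with adjusted p = 0.11 with an estimated correlation. The call of hk1 was lost with exon totals (0.0968, range 1.93e-05 to 0.0968). Insulin, IGF and thyroid axes had 15 falls and 5 rises among 35 members (16 and 5 adjusted over the list alone), with falls of dio1 (-1.37 ± 0.09) and igfbp2a (-1.42 ± 0.12) and rises of igfbp1b (1.84 ± 0.16), igfbp1a (0.98 ± 0.09), igf2b (1.34 ± 0.19), igf2a (0.80 ± 0.15) and dio2 (1.44 ± 0.25). Its adjusted p = 0.00356, with adjusted p = 0.315 with an estimated correlation. Calcium and phosphate handling had 8 falls and 2 rises among 24 members (9 and 2 adjusted over the list alone). The genes slc34a2a (-1.21 ± 0.07), stc2 (-1.41 ± 0.15) and stc1l (-1.35 ± 0.16) fell, and slc20a1b (0.51 ± 0.10) and pth1a (1.23 ± 0.28) rose. The list had adjusted p = 0.00368, with adjusted p = 0.163 with an estimated correlation.

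Stress, blood and proliferation lists were higher at 7 dpf. Stress and unfolded protein response genes rose in 17 of 26 members and fell in 1, klf9 (-0.64 ± 0.16), with 20 and 1 adjusted over the list alone. In 1 fit of all 40 libraries the call of klf9 was lost (0.401, range 6.99e-05 to 0.401). This list had adjusted p = 2.27e-09 and adjusted p = 0.0424 with an estimated correlation. Red blood cell genes rose in 10 of 15 members with 0 falls (11 and 0 adjusted over the list alone), with the erythroid transcription factor gene gata1a at 1.82 ± 0.17 and the heme synthesis gene alas2 at 1.77 ± 0.22. Its adjusted p = 3.63e-07, with adjusted p = 0.0953 with an estimated correlation. Cell cycle genes rose in 19 of 31 members with 0 falls (22 and 0 adjusted over the list alone), with hells at 1.11 ± 0.14 and mcm4 at 0.82 ± 0.12. Its adjusted p = 1.07e-08, with adjusted p = 0.335 with an estimated correlation. Bone and mineral matrix genes rose in 8 of 19 members with 0 falls (10 and 1 adjusted over the list alone), with bmp2a at 0.46 ± 0.09. Its adjusted p = 0.0179, with adjusted p = 0.324 with an estimated correlation. Immune and acute phase genes rose in 6 of 21 members, among them stat3 (1.26 ± 0.18) and socs3b (1.93 ± 0.31) of cytokine signalling, and the complement genes c3b (-1.65 ± 0.25) and c9 (-0.84 ± 0.20) fell (6 and 2 adjusted over the list alone). Its adjusted p = 0.0259, with adjusted p = 0.48 with an estimated correlation; it was 0.0667 without treated replicate 5, 0.0857 in the block by the exon table's numbers and 0.0536 with fry, over a range of 0.00375 to 0.48.

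Tissue lists of the body surface, muscle and nervous system were lower at 7 dpf. Ionocyte genes fell in 12 of 22 members with 0 rises (13 and 0 adjusted over the list alone), with atp1a1a.4 at -1.10 ± 0.08. The ionocyte list had adjusted p = 7.15e-05, with adjusted p = 0.0758 with an estimated correlation. Epidermis genes fell in 8 and rose in 2 of 19 members (9 and 3 adjusted over the list alone). Of its keratin genes krt4 (-1.31 ± 0.14) and cyt1 (-1.55 ± 0.20) fell and krt18 (0.72 ± 0.10) rose, as did the claudin gene cldne (0.32 ± 0.11). The call of cldne was lost without vehicle replicate 2 (0.126), 3 (0.132), 4 (0.0938) or 5 (0.108) or treated replicate 1 (0.104), 2 (0.118), 3 (0.142) or 4 (0.119), and with the stricter filter and each block, with a range of 1.27e-05 to 0.142. Its adjusted p = 0.00933, with adjusted p = 0.315 with an estimated correlation. Muscle genes fell in 13 and rose in 2 of 32 members (14 and 2 adjusted over the list alone), with ckmb at -0.57 ± 0.08 and the rises in mybpc2b (0.41 ± 0.08) and desma (0.33 ± 0.07). Its adjusted p = 0.00368, with adjusted p = 0.48 with an estimated correlation. Neuron and glia genes fell in 10 and rose in 2 of 31 members (10 and 2 adjusted over the list alone), with sypa at -0.48 ± 0.11 and s100b at 0.42 ± 0.10. For neurons and glia camera gave adjusted p = 0.0287, with adjusted p = 0.609 with an estimated correlation. Its call was lost without treated replicate 2 (0.0696) or 4 (0.0535). With all libraries it was lost in the block by the exon table's numbers (0.0688) and with fry (0.0821). The range was 0.000704 to 0.609.

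Of the 23 lists 18 passed at 7 dpf. Not past were vitamin D signalling and metabolism (adjusted p = 0.477), where cyp24a1 rose and gc (-2.01 ± 0.25), zgc-136333 (-1.05 ± 0.17) and vdrb fell among 15 members (1 and 3 adjusted over the list alone). The others were cartilage (adjusted p = 0.0567, 8 fell and 1 rose of 19), cholesterol biosynthesis (0.729, 6 fell and 5 rose of 20), circadian clock (0.246, 4 fell of 27, 0 adjusted over the list alone) and retinoid and pigment (0.603, 8 rose and 5 fell of 29). With exon totals the call of zgc-136333 was lost (0.0553, range 4.34e-08 to 0.0553). The cartilage list passed without vehicle replicate 2 (0.0229) or 3 (0.0203), treated replicate 2 (0.0403) or 5 (0.0451), without the shallow libraries (0.0395), in the block by the exon table's numbers (0.0207), in the replicate block (0.0242) and with fry (0.0303), over a range of 0.0203 to 0.492. The clock list passed without vehicle replicate 1 (0.00415) and without the shallow libraries (0.0259), over a range of 0.00415 to 0.75. Cholesterol biosynthesis had a median of -0.20 and a mean of 0. With an estimated correlation the list calls that held in the fit of all 10 libraries were those of fatty acids and intestine at 6 dpf, and of fatty acids, liver, intestine, exocrine pancreas and stress at 7 dpf. At 7 dpf only 2 lists passed this way in the block by the exon table's numbers, and 4 without the shallow libraries.

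**Figure D4:**
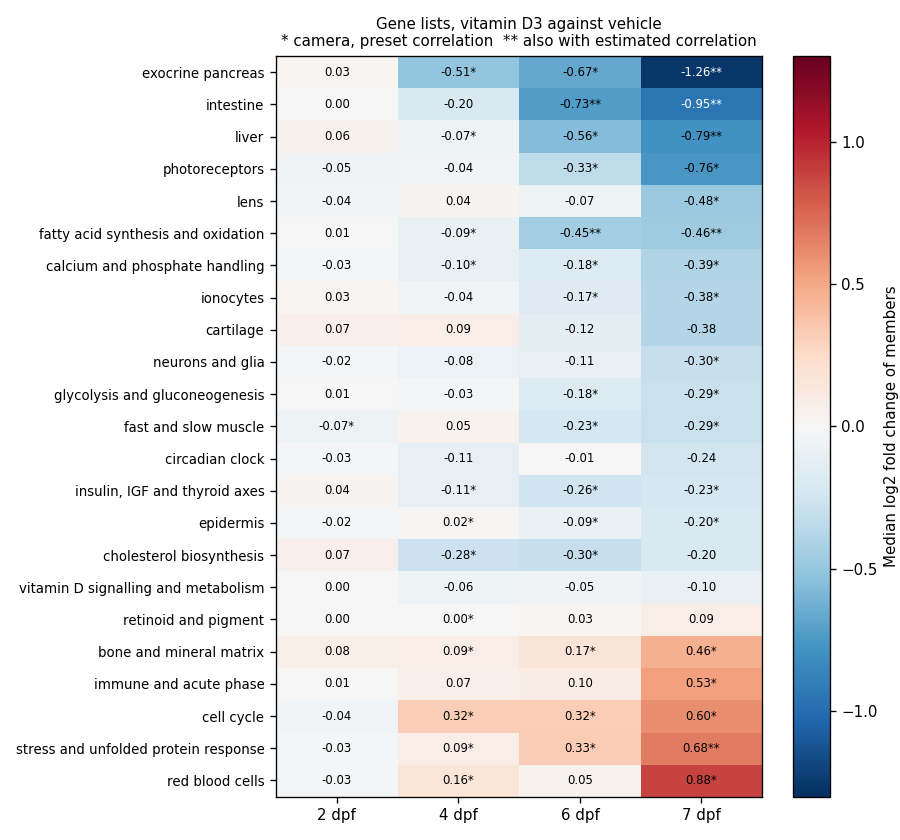
Median log2 fold change of the members of each of 23 gene lists (vertical axis) at 2, 4, 6 and 7 dpf (horizontal axis), red where treated animals are higher and blue where lower, with the value in each cell. Cells with 1 star passed camera at a preset correlation (1, 12, 15 and 18 lists) and cells with a pair of stars passed also with an estimated correlation (0, 0, 2 and 5 lists).

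Whether the response differs between ages was tested over all 40 libraries. The insulin gene ins had a treatment log2 fold change of 0.16 ± 0.19 at 2 dpf, -0.37 ± 0.13 at 4 dpf, -1.74 ± 0.18 at 6 dpf and -3.01 ± 0.24 at 7 dpf (interaction adjusted p = 6.85e-09). The transcription factor gene mycn went from -0.07 ± 0.10 at 2 dpf to 1.11 ± 0.09 at 7 dpf (adjusted p = 2.89e-08), and ezh2, which encodes a histone methyltransferase, from 0.03 ± 0.10 to 1.83 ± 0.14 (adjusted p = 1.51e-07). The pyrimidine catabolism genes dpys (0.25 ± 0.18 to -2.56 ± 0.08) and dpyd (-0.07 ± 0.10 to -1.46 ± 0.08) had adjusted p = 8.08e-08 and 1.16e-07. The other 5 genes with the smallest p were cldn5b, klf11a and slc1a4, whose log2 fold changes at 7 dpf were 1.59 ± 0.14, 3.48 ± 0.16 and 3.25 ± 0.35, and cyp4v2 and aldh1l1, at -2.54 ± 0.15 and -2.10 ± 0.09. For cyp24a1 the interaction adjusted p was 1. In edgeR 1064 of 13650 genes passed the test of 3 coefficients. Between pairs of ages the response differed in 1653 genes for 7 against 2 dpf, 913 for 7 against 4, 332 for 6 against 2, 34 for 7 against 6, 21 for 6 against 4 and 0 for 4 against 2. The total was 488 without replicate 2 of every group, 396 without replicate 3, 380 without replicate 4 and 1805 without replicate 5. It was 3667 with a block by the exon table's numbers, nested in age, and 3093 without the shallow libraries.

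Vehicle larvae give the background of development on which the treatment acts. From 2 to 4 dpf the chymotrypsin gene ctrb1 went from 0.151 ± 0.132 to 876 ± 409 CPM and ctrl from 0.0359 ± 0.0104 to 279 ± 127 CPM. The gene c6ast4 reached 82.0 ± 52.0 CPM and opn1mw1 reached 563 ± 44.7 CPM. The embryonic globin genes hbbe3 (201 ± 95.3 to 0.112 ± 0.155 CPM) and hbae1 (744 ± 136 to 89.3 ± 3.38 CPM) fell, as did the hatching enzyme gene he1a (111 ± 37.7 to 4.56 ± 6.90 CPM), coe2 (-3.07 ± 0.13) and the myelin gene plp1a (-3.04 ± 0.19). Without replicate 1 of 4 dpf the log2 fold change of he1a moved from -4.64 to -6.17 and that of hbbe3 from -11.11 to -11.99, and without replicate 2 of 2 dpf that of c6ast4 moved from 12.15 to 13.29. In edgeR 8325 of 13379 genes passed, 4288 higher and 4037 lower at 4 dpf, and 6377 (47.7%) were separated, against 0.79% by chance.

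From 4 to 6 dpf in vehicle larvae the largest rises among the genes named by rule were in fbxo32, which encodes a ubiquitin ligase of muscle wasting (4.07 ± 0.35, adjusted p = 2.19e-05), the carboxypeptidase gene cpa1 (3.61 ± 0.38), the arginase gene arg2 (3.17 ± 0.36), the uncoupling protein gene ucp1 (3.16 ± 0.38) and tat (3.05 ± 0.31). The falls named by the same rule were smaller, with the importin gene kpna2 at -1.67 ± 0.27, the pyruvate carboxylase gene pc at -1.56 ± 0.15, calrl at -1.40 ± 0.21, ndufa4 at -1.38 ± 0.13 and cpt2 at -1.37 ± 0.13. In edgeR 4838 of 13466 genes passed, 2438 higher and 2400 lower at 6 dpf, and 3173 (23.6%) were separated, against 0.79% by chance.

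From 6 to 7 dpf in vehicle larvae fbxo32 rose again (1.23 ± 0.24, adjusted p = 0.00752), as did igfbp1b (1.15 ± 0.20, adjusted p = 0.00426), tceb3 (1.73 ± 0.22), txnl1 (1.18 ± 0.10) and ubl7 (1.17 ± 0.14). The actin genes acta1b (-1.21 ± 0.14, adjusted p = 0.000366) and acta1a (-1.01 ± 0.08), col10a1 (-1.16 ± 0.23), c3b (-1.06 ± 0.18) and cmn (-1.0 ± 0.21) fell. In edgeR 1618 of 13464 genes passed, 956 higher and 662 lower at 7 dpf, and 1448 (10.8%) were separated, against 0.79% by chance. The count was 1001 without replicate 3 and 928 without replicate 4 of 6 dpf, and 2683, 930, 1019, 1034 and 933 without replicates 1 to 5 of 7 dpf in turn. Without the shallow libraries it was 3626.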

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

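The tests of lower depth, of another time of collection, of a smaller share of liver tissue and of a shared batch, with or without the shallow libraries, were chosen only after the result was seen, as were the fits without the shallow libraries and with a block by the exon table's numbers; the others were written before.

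The treated shallow library at 6 dpf (replicate 5) had 67.2 megacounts, and that at 7 dpf (replicate 5) had 13540 genes detected, each far below the other 4 of its group. Single libraries also lay far from the other 4 in the level of named genes: vehicle replicate 1 for 3 genes at 4 dpf, 2 at 6 dpf and 4 at 7 dpf, treated replicate 5 for 4 genes at 6 dpf and 6 at 7 dpf, and treated replicate 1 at 4 dpf for 1 gene. Of 156 gene and group pairs tested 20 (12.8%) held such a library, 19 of them the shallow one, where chance gives about 5%.

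The shallow library of each group differed from the rest in its expression as well as its depth. Lower depth was tested by thinning the deep vehicle libraries to its total: the gap over circadian clock genes kept at least 0.96 of its size, so depth is excluded as the cause of that gap. A different time of collection may account for it: at each age the gap over 27 clock genes (0.82, 0.90, 0.60 and 0.65 log2) lay at percentile 100 of 10000 random lists matched on expression, whose medians were 0.29, 0.18, 0.23 and 0.23. At 2 dpf the level of per1a was 0.366 CPM in the vehicle shallow library against 5.96 to 11.3 CPM in the others, and 0.731 CPM against at least 6.57 CPM in treated embryos, while at 7 dpf it was 118 CPM against 111 to 141 CPM, and 150 CPM against 110 to 142 CPM in treated larvae, with no such gap. This stays open, since the labels give no time of day and a separate clutch or preparation of these libraries, which was not tested, is open too.

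Genes of liver, exocrine pancreas, intestine and photoreceptors fell together at 7 dpf, with a median log2 fold change of -0.95 over 91 members. The tests set beforehand did not decide whether a few abundant genes shift the scaling. Upper quartile factors left the median at -0.93 but moved that of all genes only from 0.006 to 0.028. Without scaling factors the lists had -0.78 and all genes 0.178. Leaving the 100 most abundant genes out of the library sizes gave -0.87 over 83 members. It moved the median of all genes from 0.178 to 0.085, less than the bound of 0.1 set beforehand. A scaling shift moves all genes of a library alike, and at each setting the lists lay far below all genes. These values argue against scaling as the cause of their fall relative to other genes. The 27 members of the liver list ranged from -2.63 (ahsg) to 0.12 (serpina7), with an SD of 5.43 times their median SE. This excludes a smaller share of liver tissue as the whole cause only if every member is expressed in liver alone. Members expressed in other tissues too would fall less, so the test does not decide. A delay of development in treated larvae stays open: outside the 4 lists, 501 genes that rise at least 2-fold in vehicle from 4 to 6 dpf had a median treatment log2 fold change of -0.37 at 7 dpf (353 lower), and 161 that fall had 0.45 (119 higher). Among genes that change from 6 to 7 dpf in vehicle, 26 that rise had a median of 0.10 (10 lower), which goes against a delay, while the 0.54 of 50 that fall (32 higher) decides nothing, since both comparisons share the vehicle libraries of 7 dpf, and an effect of the hormone on these organs, which the design names, is also open.

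The replicate numbers of treated libraries differ between the gene and exon tables, and a batch shared by libraries with 1 number in the exon table is a candidate explanation for the larger counts of the blocked fits. Over the pairs by exon table number, deviations from the group mean correlated across genes, which are not independent replicates, at 0.25 to 0.62 at 2 dpf, 0.36 to 0.64 at 4 dpf, 0.08 to 0.50 at 6 dpf and 0.04 to 0.38 at 7 dpf, and the bound of 0.1, set after these values were seen, was missed at 6 and 7 dpf (lowest value 0.04). Among all 120 pairings the exon numbers ranked 1, 1, 2 and 2 by mean correlation (exact permutation p = 0.00833, 0.00833, 0.0167 and 0.0167, one-sided, smallest possible 0.00833), and the gene table numbers gave pairs from -0.42 to 0.41. What sets the shallow libraries apart, which share a number, is excluded as the whole cause at 2 and 4 dpf: among the deep libraries alone the exon numbers ranked 1 of 24 pairings at both ages (mean correlation 0.26 and 0.41, next best 0.25 and 0.39, exact p = 0.0417 for each, the smallest possible) and 2 of 24 at 6 and 7 dpf, and a batch stays open. No biological explanation was tested.

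The response to treatment differed between ages in 1064 of 13650 genes by the interaction test. Of 49 genes named for the treatment 37 were among them. Most of the 49 were chosen for large changes in the same libraries, so their share is no separate evidence. Of the counts of the exon table, 87.2% lie on exons without a gene name, which no comparison uses.

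Other splits of the libraries into groups of the same sizes tested whether chance can be excluded; 100 were drawn of 126 possible for each comparison of 10 libraries, the real one included. If the 10 libraries are taken as exchangeable, it can for 6 dpf (1444 genes, 1 of 100 as large, highest other 3) and for 7 dpf (3866 genes, 1 of 100, highest other 2171). On the same condition it can in vehicle for 4 against 2 dpf (8325, 1 of 100, highest other 1), 6 against 4 dpf (4838, 1 of 100, highest other 2364) and 7 against 6 dpf (1618, 2 of 100, highest other 1880). It cannot for the count of genes at 2 dpf (1 gene, 8 of 100, highest other 2150), which is no test of that 1 gene itself. For the interaction chance is not excluded (1064 genes, 2 of 40 relabellings, highest other 1727), but the relabellings cannot decide. They shuffle treatment within each age, so a draw that nearly keeps the real groups at 1 age holds a difference between ages of its own. With the block by the exon table's numbers and swaps within pairs chance is not excluded for the interaction either (3667 genes, 2 of 40, highest other 5805). The highest draw swaps 5 of 5 pairs at 7 dpf and 0 at 6 dpf. It thus keeps the difference between treated and vehicle at both ages and turns 1 of them round. Draws with 2651 and 1905 genes swap 0 pairs at 7 dpf and keep the real groups there, so these swaps cannot decide. At 2 dpf the gene is cyp24a1, which rose in 5 of 5 pairs by exon number (blocked log2 fold change 2.75 ± 0.12, adjusted p = 2.1e-06, range over the alternatives 9.96e-16 to 0.158). At 4 dpf edgeR called 0 genes (924 at an unadjusted p under 0.05, 100 in DESeq2, 30 in limma voom), so each of 100 splits has as many and the splits say nothing about chance there (highest other 2318). For the lists chance cannot be excluded at any age: 1 list at 2 dpf (96 of 100, highest other 14), 12 at 4 dpf (21 of 100, highest other 17), 15 at 6 dpf (12 of 100, highest other 19) and 18 at 7 dpf (8 of 100, highest other 19). These splits, for genes and for lists, pay no regard to the pairs by exon number. No swap within pairs was run for the lists or for the genes at 6 and 7 dpf. Where libraries share structure, the splits therefore do not exclude chance. The highest splits at 2 and 4 dpf keep 4 of 5 pairs of the exon table's numbers together and call many genes, which points to a structure of the samples; with a block by these numbers the counts were 1 and 1255. At 7 dpf the highest other split is the real one with vehicle replicate 1 and treated replicate 1 exchanged. In vehicle the highest exchange replicate 2 of 4 dpf with replicate 1 of 6 dpf, and replicate 2 of 6 dpf with replicate 1 of 7 dpf. For the blocked 1 gene at 2 dpf and 1255 genes at 4 dpf the 16 swaps within pairs are too few for a share under 0.05 (3 of 16, highest other 2, and 1 of 16, highest other 0).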

How the results depend on the processing

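The fits without the shallow libraries, with a block by the exon table's numbers and with the DESeq2 likelihood ratio test were added after the data were seen. Where a value differed, the cause was not tested, except that exon totals tested fewer genes (9148 at 6 dpf). Of the values of named genes under alternatives 9209 kept their side of the threshold, 180 passed newly, 304 no longer passed and 0 reversed; for lists these were 1391, 68, 103 and 2.

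Genes called changed by over 1.5 times as follows. With DESeq2 they were 100 at 4 dpf and 2188 at 6 dpf, and with limma voom 30 at 4 dpf, 4297 at 6 dpf, 8283 at 7 dpf, 7427 for vehicle 6 against 4 dpf, 4671 for 7 against 6 dpf and 4396 for the interaction. With the replicate block they were 921 at 6 dpf, 2517 at 7 dpf and 4404 for vehicle 7 against 6 dpf. Exon totals gave 539 at 6 dpf, 1584 at 7 dpf, 4544, 2033 and 585 for the 3 vehicle steps and 324 for the interaction. Without the shallow libraries they were 18 at 4 dpf, 3532 at 6 dpf, 7626 at 7 dpf, 3626 for vehicle 7 against 6 dpf and 3093 for the interaction. The block by the exon table's numbers gave 1255 at 4 dpf, 3457 at 6 dpf and 3667 for the interaction, and 1 fit of all 40 libraries gave 27 at 4 dpf.

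Leaving out 1 library gave 0 to 1 genes at 2 dpf, 0 to 9 at 4 dpf, 849 to 2310 at 6 dpf, 2773 to 5678 at 7 dpf, 7685 to 8484, 3819 to 6001 and 928 to 2683 for the vehicle steps. For the interaction 1 replicate number was left out of every group at once, which gave 380 to 1805. Lists called ranged from 1 to 9 at 2 dpf, 4 to 14 at 4 dpf, 14 to 17 at 6 dpf and 17 to 19 at 7 dpf. With an estimated correlation 0, 0, 2 and 5 lists passed at 2, 4, 6 and 7 dpf, and with fry 0 at 2 dpf and 2 at 4 dpf. At 2 dpf 2 lists passed with the replicate block, 4 without the shallow libraries and 3 with the block by the exon table's numbers. The direction reversed past the threshold for the cell cycle list at 2 dpf without vehicle replicate 1 (adjusted p = 0.000159, over all libraries left out 9.33e-05 to 0.915) and for the circadian clock list at 2 dpf without treated replicate 5 (adjusted p = 0.0323, over all libraries left out 0.000159 to 0.945); the cause was not tested. The planned DESeq2 Wald test of the interaction was not run; the likelihood ratio test called 1472 genes. For genes with many counts replicate spread, not counting error, limits the calls at this depth.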

Other observations

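The test of stress genes in this part was written before its result was seen.

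Among the 10 genes with the smallest interaction p-values, only ins stands on a fixed list. The others, among them dpys, dpyd, aldh1l1 and ezh2, stand on none. At 6 dpf the log2 fold change was -1.59 ± 0.27 for dpys, -1.10 ± 0.11 for dpyd and -1.3 ± 0.18 for aldh1l1, and 1.11 ± 0.16 for ezh2. In cldn5b, which encodes a claudin of blood vessels, it was 1.09 ± 0.11 at 6 dpf and 1.59 ± 0.14 at 7 dpf (interaction adjusted p = 8.08e-08).

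A hypothesis was that the higher stress genes at 7 dpf may reflect a delay of development, so that treated larvae would hold the level of a younger vehicle larva. Of 17 members of the list that rose, 12 had a treated mean above the highest vehicle mean of the 4 ages by more than 2 SE. This explanation forbids that if vehicle levels were no higher between the ages sampled. The SE is that of the treated libraries and leaves out the error of the vehicle mean. For hsp70l the treated mean was 75.2 ± 18.4 CPM (SE) against 4.06 CPM, and for igfbp1b it was 1130 ± 83.1 CPM against 317 CPM. In 4 members, among them pdia4 (29.7 against 58.6 CPM), the treated mean lay within the range of the vehicle means.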
